A study of Mus musculus with 12 samples.

How the data were processed

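RNA was measured on Affymetrix whole-transcript arrays in cells sorted from mouse spleens, per the labels' protocols. The sort used CD3 and CD4 for T cells and Gr-1 and CD11b for granulocytes. The mice either carried ITK-SYK, a fusion of the kinases ITK and SYK found in human peripheral T-cell lymphoma, or were wild-type controls. The 12 arrays formed 4 groups of 3: control T cells, ITK-SYK T cells, control granulocytes and granulocytes of ITK-SYK mice. Each array is named by the sample number in the labels (S1 and so on). The genotype label of the granulocytes is that of the mouse.

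The deposited values are log2 expression values made with RMA in the R package oligo, per the submitters' processing notes. RMA corrects the background, normalizes the quantiles between arrays and summarises the probes of a probeset. The versions, the annotation and any genome build are not given in the sources used here. The log2 scale of the deposited values was also checked against their range and the nearly equal medians of the arrays. Each array had 32471 probesets. No columns were identical, and arrays of a group correlated at 0.975 to 0.993 across probesets. The number of arrays limits the precision of every value.

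Gene symbols came from the platform annotation. There were 22943 probesets with 1 gene symbol, 1737 with several and 7791 with none. Only those with 1 symbol were named. By their Entrez numbers, 99.3% of the genes matched the reference gene table, and 0 symbols changed. Where a gene had several probesets (828 genes), the one with the highest mean over the 12 arrays was used, which left 21957 genes. No filter on dim genes was applied. No single-symbol probeset was assigned to Itk, so Itk was not analysed here.

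All 12 arrays entered 1 fit of 4 group means in limma 3.58.1 (R 4.3.3, the package data.table in version 1.17.8, statmod 1.5.0), with default empirical Bayes moderation. The residual degrees of freedom were 8 and the prior ones 5.25, so that each test had 13.3. Standard errors (SE) are those of the fit, and n = 3 arrays in each group throughout. The comparisons were ITK-SYK minus control in T cells, the same in granulocytes, the difference between these 2 genotype differences, and control T cells minus control granulocytes. Adjusted p-values are Benjamini-Hochberg over the 21957 genes of a comparison, and a gene passed at an adjusted p below 0.05. Neither a mouse shared between T cells and granulocytes nor a batch is given in the labels, so no block was used. The labels do not say that samples of a group came from different mice. The p-values therefore measure only the spread between these samples, which may be technical.

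Groups of genes were 50 lists fixed before the data were examined, as were the groups, the tests, the other settings and the rule for naming genes. Each list had at least 5 measured genes and was tested with camera in limma, with a preset correlation between genes of 0.01 and Benjamini-Hochberg adjustment over the lists. Camera with an estimated correlation and fry were alternatives. Counts of members are over all genes tested unless said to be adjusted over the list alone. The list of immunoglobulin genes was drawn up from a symbol pattern that also takes in Ighmbp2, a helicase gene.

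The rule for named genes took, per genotype comparison, the 10 largest changes in each direction among genes that passed and whose arrays did not overlap between the groups. Predicted genes, small RNAs, olfactory and vomeronasal receptors and antigen receptor segments were left out of that ranking. For lists that passed camera, or with 3 or more passing members, up to 4 members with the lowest adjusted p were taken. For the difference between cell types the 5 largest in each direction were taken. Genes outside this rule are said to have been chosen after their values were seen.

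The procedure was tested on simulated data made from the arrays' group means and spread, with 5 simulated sets of 21957 genes. Of 250 genes changed by a log2 value of 1, the share found was 83.2% in the T-cell comparison, 87.2% in the granulocyte comparison and 49.2% in the difference between cell types. At a log2 value of 0.58 these shares were 42.4%, 42.0% and 14.0%, and at 2 they were 99.2%, 98.0% and 96.0%. The share of false calls among all calls was 5.58%, 5.54% and 4.46%. A list of 20 genes shifted by a log2 value of 0.5 was found in 5 of 5 sets in each comparison, and 0 of 245 unshifted lists passed. The simulated genes varied independently of each other, while the estimated correlation in the real lists reached 0.53 (eosinophil markers). The simulation therefore does not show how often correlated lists pass falsely.

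The settings fixed beforehand were quantile normalization again over all arrays or within a cell type, subtraction of array medians, cyclic loess, leaving out the dimmest 25% or 50% of genes, the mean of all probesets of a gene, every probeset on its own, empirical Bayes with a trend or with a trend and robust, array quality weights, a fit of each cell type alone, an adjusted p below 0.01, a fold change of at least 2, and leaving out each array. A fit without arrays S10 and S6, whose quality weights were the lowest, was added after the data were seen. Where an array is left out, its group keeps 2 arrays and the spread is pooled over the 4 groups.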

Results

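The series profiled CD4 T cells and granulocytes from the spleens of mice with the ITK-SYK fusion kinase and of wild-type mice, with 3 arrays in each of 4 groups. The design asks how the fusion changes the T cells, and how the granulocytes of the same mouse line differ from those of controls. Expression is given as RMA values on the log2 scale. Differences are log2 changes, ITK-SYK minus control, with the standard error (SE) of the limma fit. Array medians lay between 3.46 and 3.59. Where a group's mean was below 3.46, the lowest array median and not a measured detection limit, the size of a change is uncertain. In T cells this holds for Klk1b27, Il18rap, Il2, Il4, Il23r, Maf, Klrg1, Gzma, Entpd1, Lyz2, Anxa1 and S100a8, and in granulocytes for Ear6, Prg3, Cpa3, Phxr4, Nqo1 and Cd36. In ITK-SYK T cells, array S10 correlated at 0.975 with both other arrays of its group, the lowest value of any array. The quality weight was 0.29 for S10 and 0.60 for S6, a control granulocyte array, and 0.89 to 1.90 for the other 10.

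The genes of the fusion partners were looked at first. Syk, a tyrosine kinase used by antigen and Fc receptors of B and myeloid cells, measured 3.73, 3.66 and 3.31 in control T cells S1, S4 and S7. It measured 3.63, 3.85 and 4.01 in ITK-SYK T cells S10, S13 and S16. The change was 0.26 ± 0.14 (adjusted p = 0.301). In granulocytes Syk measured 7.99, 8.12 and 8.06 in control arrays S3, S6 and S9, and 7.85, 7.84 and 8.10 in S12, S15 and S18 of ITK-SYK mice, a change of -0.13 ± 0.14 (adjusted p = 0.827). The labels do not state whether the array's probes match the transgene, so Syk checks neither its presence nor its absence. Itk was not analysed here.

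The cell-type labels were set against marker lists in the control arrays. All 16 measured T-cell markers were higher in control T cells than in control granulocytes, with a median difference of 4.53 (adjusted p = 6.02e-18 by camera and 0.0204 with an estimated correlation). Of 22 neutrophil markers, 21 were lower in T cells, with a median of -7.30 (adjusted p = 4.19e-20, and 0.0423 with an estimated correlation). Adjusted over the list alone, these counts were again 16 and 21. In total 4441 genes were higher and 3247 lower in control T cells. Of 17 B-cell markers, 16 were lower in T cells than in granulocytes, with a median of -3.53 (17 adjusted over the list alone; adjusted p = 0.0204 with an estimated correlation).

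Lilrb4a, Casp1 and S100a6 were the genes most increased in ITK-SYK T cells. Lilrb4a, an inhibitory immunoglobulin-like receptor, rose by 5.25 ± 0.69 (38.1-fold, adjusted p = 0.00073), with control array S1 at 6.98 against 3.42 and 3.31 in S4 and S7. Casp1, the inflammasome protease, rose by 4.15 ± 0.33 (17.7-fold, adjusted p = 2.56e-05), and Ifng, the cytokine of type 1 immunity, by 3.83 ± 0.40 (14.2-fold, adjusted p = 0.000138). Ifng measured 8.76, 6.64 and 6.66 in S10, S13 and S16 and 3.37 to 3.72 in controls. The calcium-binding proteins S100a6 and S100a4 rose by 4.13 ± 0.33 and 3.98 ± 0.33, the myosin Myo1f by 3.96 ± 0.24 and the calcium pump Atp2b4 by 3.67 ± 0.30. The chemokine receptor Cxcr6 rose by 3.66 ± 0.27, the interleukin-18 receptor chain Il18rap by 3.95 ± 0.34 and the kallikrein Klk1b27 by 3.70 ± 0.42. Each of these 10 genes passed with any 1 array left out, and each was highest in S10 among the T-cell arrays. Of the 10, Lilrb4a, Myo1f, S100a6, Casp1 and Il18rap are also abundant in control granulocytes (means of 11.74, 10.71, 10.69, 8.43 and 8.12), and neutrophil markers were likewise highest in S10 (a list median of 5.42 against 3.65 to 3.75 in controls). Of these 5, Lilrb4a, Myo1f and S100a6 measured 9.4, 8.1 and 9.3 in S13 and 9.8, 8.3 and 9.3 in S16. Casp1 and Il18rap measured 8.0 and 6.2 in S13 and 8.0 and 6.5 in S16. The median of the neutrophil markers there was 4.0 and 3.9, against 11.3 to 11.4 in control granulocytes. These levels argue against neutrophil RNA as the sole source of the 5 genes in S13 and S16.

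Genes lowered most in ITK-SYK T cells changed less. Arhgap29, a Rho GTPase-activating protein, fell by 1.99 ± 0.33 (adjusted p = 0.00328), the kinase Mapk11 by 1.78 ± 0.34, the histone gene H4f16 by 1.75 ± 0.31 and the prostacyclin receptor Ptgir by 1.62 ± 0.27. Igsf23 fell by 1.57 ± 0.21 and Tlcd1 by 1.53 ± 0.25. Mapk11 missed the threshold when T cells were fitted alone (adjusted p = 0.0653, with a range of 4.63e-05 to 0.0653 over 24 alternatives). The RNA sensor Tlr7 (-1.74 ± 0.40), the thymocyte gene Itm2a (-1.67 ± 0.40), the adhesion molecule Chl1 (-1.60 ± 0.41) and the ubiquitin ligase Rnf122 (-1.54 ± 0.36) also fell. These 4 lost their calls without control array S1, S4 or S7, with adjusted p up to 0.0713, 0.094, 0.112 and 0.0796.

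**Figure D1:**
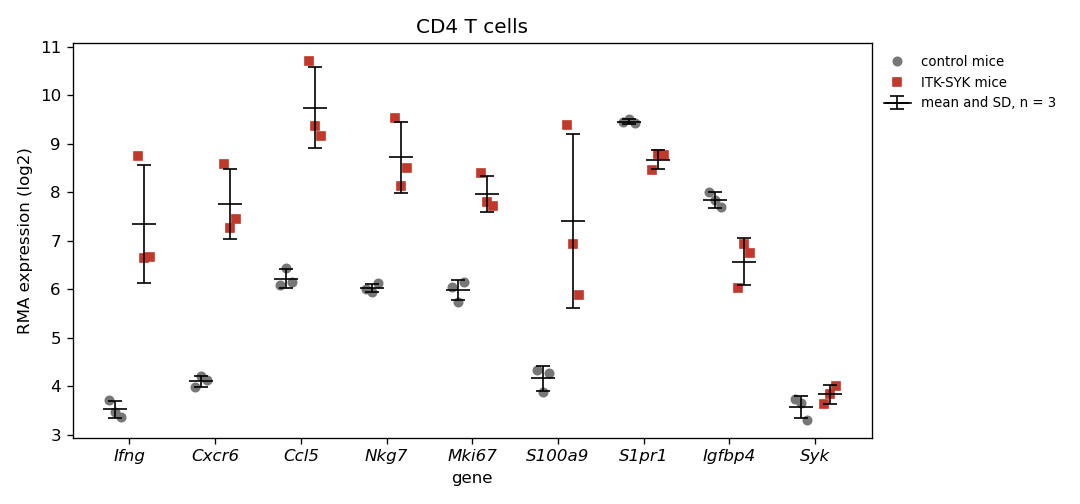
RMA expression on the log2 scale (vertical axis) of 9 genes in CD4 T cells, with points for the 3 arrays of each group and black marks for mean and SD. All ITK-SYK arrays lie above all control arrays for Ifng, Cxcr6, Ccl5, Nkg7, Mki67 and S100a9 and below them for S1pr1 and Igfbp4, while Syk overlaps.

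Type 1 helper and cytotoxic genes rose in part, and the type 2 helper list did not pass. Of 15 measured type 1 helper T-cell genes 9 rose and 0 fell (10 and 0 adjusted over the list alone), with a median change of 1.56. The list's adjusted p was 1.18e-12, but 0.14 with an estimated correlation. Beside Cxcr6 and Il18rap, the interleukin-18 receptor Il18r1 rose by 3.17 ± 0.27 and the chemokine receptor Cxcr3 by 2.54 ± 0.23. Of 21 cytotoxic effector genes 10 rose (11 rose and 1 fell adjusted over the list alone), with a median of 0.91, or 0.37 without S10 (adjusted p = 5.4e-10, and 0.14 with an estimated correlation). They included the chemokine Ccl5 (3.53 ± 0.37), the granule protein Nkg7 (2.70 ± 0.26), the granzyme Gzmk (2.64 ± 0.28) and the receptor Klrg1 (2.41 ± 0.23). Of 14 type 17 helper T-cell genes 5 rose, among them the interleukin-23 receptor Il23r (1.04 ± 0.22), Ltb4r1, Tmem176b and Ahr. The count was 3 without S1 or S4, and 7 adjusted over the list alone. The median was 0.56, or 0.45 without S10 (adjusted p = 7.96e-07, and 0.14 with an estimated correlation). Ltb4r1 measured 6.12, 5.65 and 5.55 in S10, S13 and S16, 4.16 to 5.03 in control T cells and 9.81 to 10.26 in control granulocytes. It did not pass when T cells were fitted alone (adjusted p = 0.0568). The call of Ahr was lost with T cells fitted alone or without S1, S4, S7 or S10 (adjusted p up to 0.0872). This list's median level was 5.41 in S10, 3.93 and 3.92 in S13 and S16 and 3.65 to 3.68 in controls, and Il23r did not pass when T cells were fitted alone (adjusted p = 0.0735, with a range of 0.000484 to 0.0735 over the 22 alternatives that kept it). Of 12 type 2 helper genes 2 rose and 0 fell, or 1 rose without S1, S4, S7, S10 or S16 (2 and 3 adjusted over the list alone), with a median of -0.18 (adjusted p = 0.976). Natural killer cell markers, which share Nkg7 with the cytotoxic list, had 4 of 14 rise and 1 fall (adjusted p = 0.00168, and 0.183 with an estimated correlation). Their other leading members were the granzyme Gzma (1.89 ± 0.29) and the cytokine receptor chain Il2rb (1.25 ± 0.24). The 1 fall was lost without S1, S4, S7, S10, S13, S9, S12, S15 or S18.

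Follicular helper, inhibitory and cytokine genes rose in part. Of 19 follicular helper T-cell genes 7 rose and 1 fell (8 and 2 adjusted over the list alone), with a median of 0.31, or 0.21 without S10 (adjusted p = 0.00168, and 0.179 with an estimated correlation). The transcription factor Maf rose by 2.51 ± 0.22, the type 2 cytokine Il4 by 2.41 ± 0.23, the CD30 ligand Tnfsf8 by 2.01 ± 0.27 and the costimulator Icos by 1.89 ± 0.29. Among 22 inhibitory receptors and exhaustion regulators 5 rose and 1 fell (6 and 1 adjusted over the list alone), with a median of 0.14 (adjusted p = 0.00766, and 0.14 with an estimated correlation). Besides Lilrb4a, these were led by the inhibitory receptor Tigit (2.56 ± 0.24), the transcription regulator Id2 (1.13 ± 0.15) and the ectonucleotidase Entpd1 (1.65 ± 0.29; adjusted p = 0.0515 with T cells fitted alone, and 0.00363 to 0.0515 over 24 alternatives), and the 1 fall was lost without S1, S4, S7, S10 or S13 and without 4 granulocyte arrays. Of 33 cytokines and chemokines made by T cells that act on myeloid cells 8 rose and 1 fell, but 5 rose without S1 or S4 and 0 fell without S1 (10 and 1 adjusted over the list alone). The median was 0.23, or 0.15 without S10 (adjusted p = 3.74e-05, and 0.14 with an estimated correlation), and the members with the lowest p were Il4, Ccl5, Ifng and Tnfsf8.

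Some genes of dividing cells were higher and some of resting T cells lower. Of 43 genes of G2 and mitosis 18 rose and 0 fell (22 and 0 adjusted over the list alone), with a median of 0.56 (adjusted p = 4.47e-17, and 0.183 with an estimated correlation). In control arrays 42 of the 43 were lower in T cells than in granulocytes, with a median of -2.69. The list's median level was 5.12, 5.38 and 5.20 in S10, S13 and S16, 4.26 to 4.42 in control T cells and 7.30 to 7.80 in control granulocytes. The proliferation antigen Mki67 rose by 1.98 ± 0.17, the cyclin Ccnb2 by 1.56 ± 0.16, the topoisomerase Top2a by 1.51 ± 0.17 and the kinesin Kif15 by 1.27 ± 0.13. Of 38 genes of DNA replication and S phase 8 rose, with the helicase subunit Mcm6 at 0.72 ± 0.13, but 4, 3 and 3 without S1, S4 and S7 (10 rose and 3 fell adjusted over the list alone). That list had an adjusted p of 0.0245 and 0.669 with an estimated correlation, and it lost its call without S7, S13 or S16 (0.0719, 0.175 and 0.0605). Of 24 naive and resting T-cell genes 9 fell and 0 rose, but 4 and 5 without S1 and S4 (12 fell and 1 rose adjusted over the list alone). Their median was -0.71, or -0.34 without S10 (adjusted p = 6.6e-07, and 0.246 with an estimated correlation), and their median level was 6.93 in S10, 8.12 and 7.92 in S13 and S16 and 8.07 to 8.29 in controls. They included Igfbp4 (-1.27 ± 0.20), the interleukin-6 receptor Il6ra (-0.99 ± 0.17), the egress receptor S1pr1 (-0.79 ± 0.13) and the sialyltransferase St8sia6 (-1.19 ± 0.23).

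A minority of MYC target and ribosome biogenesis genes fell. Of 34 members 8 fell and 0 rose (14 and 0 adjusted over the list alone), with a median of -0.34 (adjusted p = 1.55e-07, and 0.183 with an estimated correlation). The nucleolar proteins Pes1 and Nolc1 fell by 0.93 ± 0.14 and 0.87 ± 0.17, and the spermidine synthase Srm by 0.84 ± 0.15. The count was 4, 4, 5 and 5 without S1, S4, S7 and S10. Among activation genes of the T-cell receptor 4 of 26 rose and 4 fell, or 1 fell without S1 or S4 (5 and 6 adjusted over the list alone), and the list did not pass (adjusted p = 0.317). Icos, Il2 (1.51 ± 0.27) and the adhesion receptor Cd44 (1.29 ± 0.24; adjusted p = 0.0558 with T cells fitted alone, and 0.00212 to 0.0558 over 24 alternatives) rose, and the transcription factor Myc fell by 0.93 ± 0.17. Glycolysis genes had a median of -0.17 and 1 of 21 fell (adjusted p = 0.0272, and 0.534 with an estimated correlation), which was lost without S1 or S4 (0.0547 and 0.0519), and 0 fell without S1, S7 or S10. Of 18 regulatory T-cell genes 3 rose and 4 fell (6 and 4 adjusted over the list alone), and the list did not pass (adjusted p = 0.311). The lineage factor Foxp3 fell by 0.79 ± 0.13 and Lrrc32, which anchors TGF-beta, by 0.70 ± 0.11, while Tigit and the integrin Itgae (1.87 ± 0.18) rose.

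Some antigen receptor segments and a few interferon genes were lower in ITK-SYK T cells. Of 8 T-cell receptor variable segments 3 fell (5 adjusted over the list alone), with a median of -0.67 (adjusted p = 0.00223, and 0.14 with an estimated correlation). Trbv13-2 fell by 1.42 ± 0.22 and Trav14d-3-dv8 by 0.86 ± 0.15. Trav7-4 fell by 1.10 ± 0.13 on the probeset used, while its other 2 changed by 0.61 and -1.73. Segments of this family are near-identical and the probes may not tell them apart. Of 33 type I interferon response genes 6 fell and 0 rose (9 and 0 adjusted over the list alone), with a median of -0.18 (adjusted p = 0.00766, and 0.497 with an estimated correlation). The antiviral synthetase Oas2 fell by 1.13 ± 0.21 and the nucleic acid sensor Zbp1 by 0.63 ± 0.14, which lost its call after cyclic loess or without S1, S4, S7 or S10 (adjusted p of 0.0113 to 0.0639 over 24 alternatives). The count of falls was 1, 1, 1, 2 and 3 without S1, S4, S7, S10 and S16, and the list did not pass without S16 (0.155), after renewed quantile normalization, after cyclic loess or without the dimmest 50% of genes (0.000912 to 0.258 over 24 alternatives). Of 30 interferon-gamma response genes 3 fell and 0 rose, or 1 fell without S1, S4, S7 or S16, and the list did not pass (median -0.07, adjusted p = 0.361).

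Some transcripts of myeloid cells were higher in the arrays of ITK-SYK T cells, most of all in S10. Of 22 neutrophil markers 4 rose (6 adjusted over the list alone), with a median of 0.61, or 0.22 without S10 (adjusted p = 1.24e-05, and 0.362 with an estimated correlation). The list's median level was 5.42 in S10, 4.0 in S13, 3.92 in S16 and 3.65 to 3.75 in controls. S100a9, an abundant neutrophil protein, rose by 3.24 ± 0.58 and measured 9.39, 6.93 and 5.89 in S10, S13 and S16 against 3.87 to 4.34 in controls. It did not pass when T cells were fitted alone (adjusted p = 0.058, with a range of 5.02e-05 to 0.058 over 24 alternatives). Its partner S100a8 rose by 2.74 ± 0.72, with 8.36 in S10, and lost its call without S1, S4, S7, S9, S12, S15 or S18 (adjusted p up to 0.129). The count of 4 was 2 without any of these 7 arrays. Of 21 secondary granule genes 4 rose, with a median of 0.51, or 0.20 without S10 (adjusted p = 3.23e-05, and 0.362 with an estimated correlation). They were led by the annexin Anxa1 (2.56 ± 0.39) and the peptidoglycan receptor Pglyrp1 (1.71 ± 0.30). Of 16 primary granule genes 4 rose (0.00637 and 0.352), among them Nkg7 and the lysozyme Lyz2 (3.09 ± 0.41). Nkg7 is also in the cytotoxic list. It measured 9.54, 8.12 and 8.5 in S10, S13 and S16, above the 6.72 to 7.01 of control granulocytes. Its rise is therefore not evidence of myeloid RNA in these arrays. Monocyte markers rose in 3 of 23 (adjusted p = 0.00789, and 0.497 with an estimated correlation), among them S100a4 and the chemokine receptor Ccr2 (2.24 ± 0.35), which are also made by activated T cells. Macrophage markers passed (0.00766, and 0.512 with an estimated correlation), but not without S10 (0.128). Of these 19 only Apoe rose (0.48 ± 0.13), and 0 rose without S1, S4, S7, S10, S13, S9, S12 or S15.

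In total 577 genes were higher and 1035 lower in ITK-SYK T cells, 7.34% of the genes tested, of which 246 and 117 changed at least 2-fold. Groups did not overlap for 25.4% of genes, against 10% by chance. The split depended on the scaling, with 687 higher and 669 lower after renewed quantile normalization, 631 and 614 when that was done within each cell type, and 747 and 560 after cyclic loess. Leaving out control array S1, S4 or S7 gave 331, 338 and 356 higher and 304, 385 and 562 lower, and leaving out S10 gave 508 and 630. Of 50 lists 19 passed upward and 5 downward, and 0 with an estimated correlation.

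In granulocytes of ITK-SYK mice, some transcripts of eosinophils and basophils were among the most increased. Prg2, the eosinophil major basic protein, rose by 5.32 ± 0.42 (39.9-fold, adjusted p = 3.49e-05), and measured 8.13, 10.2 and 10.2 in S12, S15 and S18 against 3.97 to 4.28 in controls. The lipoxygenase Alox15 rose by 4.54 ± 0.50 (23.3-fold). The ribonuclease Ear6 rose by 3.93 ± 0.39 and the major basic protein homologue Prg3 by 2.57 ± 0.40, with uncertain sizes (control means of 2.34 and 2.82). Of 11 eosinophil markers these 4 rose (7 adjusted over the list alone), with a median of 0.80 and a mean of 1.77 (adjusted p = 5.4e-12, and 0.0711 with an estimated correlation). Array S12 lay 0.97 below the mean of S15 and S18 in the median of this list's members. Siglecf (0.80 ± 0.21), Ccr3 (0.42 ± 0.37) and Il5ra (-0.11 ± 0.30), surface receptors of eosinophils chosen after their values were seen, did not pass over all genes tested (adjusted p = 0.096, 0.78 and 0.949). Nor did the peroxidase gene Epx, likewise chosen afterwards (1.07 ± 0.25, adjusted p = 0.0576, with a control mean of 3.03). Epx and Siglecf were among the 7 that rose when adjusted over the list alone. Of 15 basophil and mast-cell markers 3 rose and 1 fell (5 and 1 adjusted over the list alone), with a median of 0.29 (adjusted p = 2.63e-05, and 0.023 with an estimated correlation). The basophil protease Mcpt8 rose by 3.21 ± 0.25 (9.27-fold, adjusted p = 3.12e-05), the mast-cell carboxypeptidase Cpa3 from a mean of 3.40 to 5.40 (SE of the change 0.31) and the protease Prss34 by 1.72 ± 0.17. The stem cell factor receptor Kit fell by 0.92 ± 0.15.

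Interferon-induced genes were higher in the same granulocytes. Oasl2 and Zbp1 rose by 2.49 ± 0.16 and 2.21 ± 0.14 (5.61-fold and 4.61-fold, adjusted p = 9.51e-06 for both), Ifit1 by 1.40 ± 0.16 and Xaf1 by 1.31 ± 0.14. Of 33 type I interferon response genes 18 rose and 0 fell (28 and 0 adjusted over the list alone), with a median of 0.64 (adjusted p = 4.65e-31, and 0.0188 with an estimated correlation). The count was 11, 9 and 9 without S9, S12 and S15, and 11 after renewed quantile normalization, where the median was 0.54. Of 30 interferon-gamma response genes 11 rose and 3 fell (21 and 3 adjusted over the list alone), with a median of 0.68 (adjusted p = 1.76e-17, and 0.0291 with an estimated correlation), and 1 fell without S6, S15 or S18. The immunity GTPases Igtp and Gbp7 rose by 1.94 ± 0.18 and 1.84 ± 0.19, the MHC class I transactivator Nlrc5 by 1.75 ± 0.18 and the peptide transporter Tap1 by 1.09 ± 0.12. H2-Q5, a class I gene with close paralogs that share sequence, rose by 2.01 ± 0.21.

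A few genes of granulocyte growth factor signalling and granules rose. Of 23 genes of G-CSF and GM-CSF receptor signalling 5 rose, or 3 without S15 (7 rose and 2 fell adjusted over the list alone), with a median of 0.22 (adjusted p = 9.19e-07, and 0.0235 with an estimated correlation). Csf2rb2, a chain of the interleukin-3 receptor, rose by 1.78 ± 0.26, the coactivator Bcl3 by 0.90 ± 0.13 and the feedback inhibitor Socs1 by 0.80 ± 0.14. The chemoattractant Prok2 rose by 2.23 ± 0.22 and the endothelial lipase gene Lipg by 2.74 ± 0.29. Of 31 tertiary granule and mature neutrophil genes 3 rose, led by the protease Asprv1 (1.71 ± 0.29), but 1 without S1, S4, S7, S6, S9, S12 or S15 (10 rose and 1 fell adjusted over the list alone; median 0.34, adjusted p = 1.78e-06, and 0.114 with an estimated correlation). Of 16 primary granule genes 3 rose (4 adjusted over the list alone), Elane (1.20 ± 0.22), Prtn3 (1.38 ± 0.31) and Mpo (0.96 ± 0.22), enzymes of early neutrophil granules. That count was 0 without S6 or S15 and 1 without S1, S7, S16, S9 or S12, and the list had an adjusted p of 0.000972, and 0.184 with an estimated correlation. Of 21 secondary granule genes 1 rose, or 0 without S6, S12 or S15, and the list did not pass (adjusted p = 0.0666). Of 21 glycolysis genes 1 rose, the regulator Pfkfb4 (0.90 ± 0.13), against 7 adjusted over the list alone (median 0.33, adjusted p = 2.68e-07, and 0.114 with an estimated correlation). Of 43 mitotic genes none passed, with Kif20a at 0.74 ± 0.21 (adjusted p = 0.118), and the list's adjusted p was 0.000811, 0.518 with an estimated correlation and 0.0563 without S6.

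Most B-cell markers and some T-cell genes were lower in granulocytes of ITK-SYK mice. Of 17 B-cell markers 14 fell and 0 rose (15 and 1 adjusted over the list alone), with a median of -1.60 (adjusted p = 5.52e-32, and 0.0144 with an estimated correlation). The IgM Fc receptor Fcmr fell by 2.07 ± 0.15, from a mean of 9.25 to 7.18, the IgE receptor Fcer2a by 2.21 ± 0.18, the complement receptor Cr2 by 2.33 ± 0.23 and the B-cell factor Ebf1 by 2.06 ± 0.22. Cd180 (-2.05 ± 0.28) and Rasgrp3 (-2.13 ± 0.24), which are active in B cells, and Ralgps2 (a mean of 6.35 to 4.35, SE of the change 0.20) were also among the 10 largest falls. Slamf6, a lymphocyte receptor, changed by -2.06 ± 0.29 but did not pass as the mean of its probesets (adjusted p = 0.115, with a range of 6.76e-05 to 0.115 over 24 alternatives). Of 16 T-cell markers 6 fell (median -0.56, adjusted p = 2.7e-13, and 0.0291 with an estimated correlation), among them Cd3g (-1.79 ± 0.21), Cd2 (-1.62 ± 0.18) and Cd3e (-1.27 ± 0.16). Of 26 genes of proximal T-cell receptor signalling 12 fell (13 adjusted over the list alone), led by the adaptor Grap2 (-1.93 ± 0.14), with a median of -0.41 (adjusted p = 1.23e-17, and 0.0291 with an estimated correlation). Of 14 MHC class II genes 5 fell (9 adjusted over the list alone), or 3 without S6, S9, S15 or S18, with a median of -0.58 (adjusted p = 8.4e-12, and 0.0532 with an estimated correlation). H2-DMb1 fell by 1.23 ± 0.17, H2-Ab1 by 0.94 ± 0.16 and the class II transactivator Ciita by 0.90 ± 0.16. Of 205 genes that fell in granulocytes, 93 (45.4%) were at least 2-fold higher in control T cells than in control granulocytes, against 8.82% of all genes and 14.4% of the genes that rose.

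Other falls in granulocytes were in genes outside the lymphocyte lists, though many of these genes are also higher in T cells. In control arrays 29 of the 34 genes of MYC targets and ribosome biogenesis were higher in T cells than in granulocytes. So were 40 of the 55 ribosomal protein genes. Phxr4 measured 7.5 to 8.3 in control T cells and 4.7 to 6.4 in control granulocytes. A smaller amount of lymphocyte RNA is not excluded as a source of the falls of these genes. The fatty acid desaturase Scd1 fell by 2.37 ± 0.23 (adjusted p = 0.000146) and Phxr4 by 2.48 ± 0.33. Unlike Phxr4, Scd1 was lower in control T cells (2.09 to 2.70) than in control granulocytes (6.37 to 6.96). Of 34 genes of MYC targets and ribosome biogenesis 3 fell (10 adjusted over the list alone), with Nop58 at -0.75 ± 0.14 (median -0.26, adjusted p = 4.56e-08, and 0.114 with an estimated correlation), but 0 without S6 and 1 without S12, S15 or S18. Of 55 ribosomal protein genes none passed, with Rpl35 at -0.43 ± 0.12 (adjusted p = 0.104), and the list had a median of -0.17 (adjusted p = 3.51e-05, and 0.28 with an estimated correlation). The integrin Itgax, a dendritic-cell and phagocyte marker, fell by 1.55 ± 0.20. It too was lower in control T cells (3.35 to 3.46) than in control granulocytes (5.92 to 6.79). Dendritic-cell markers fell in 3 of 19 (adjusted p = 0.00278, and 0.0516 with an estimated correlation). Of 22 neutrophil markers 2 rose, Elane and Mpo, with a median of 0.19 (adjusted p = 0.0052, and 0.518 with an estimated correlation). Both lost their calls without S6, S9 or S15, with adjusted p up to 0.08 and 0.225, and 1 rose without S1, S4, S7, S16, S12 or S18.

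**Figure D2:**
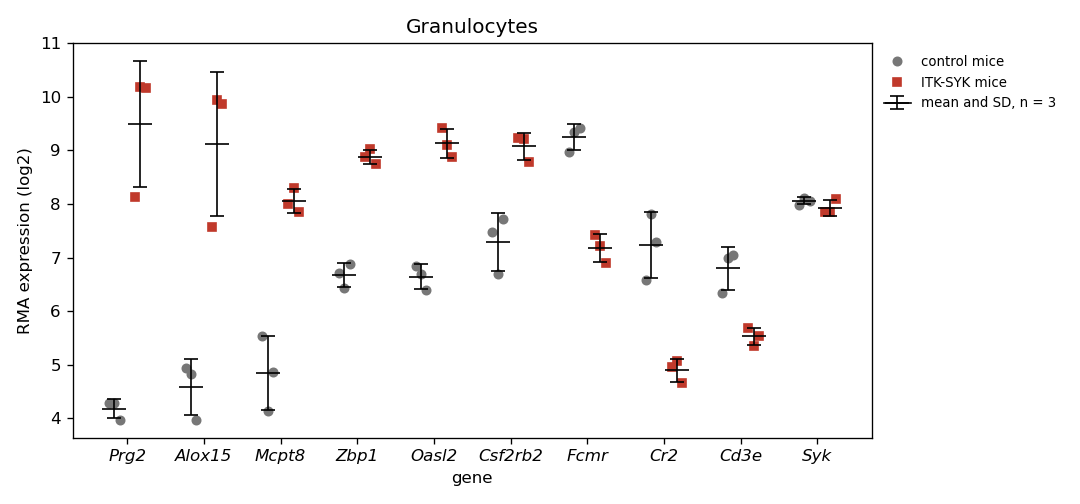
RMA expression on the log2 scale (vertical axis) of 10 genes in granulocytes, with points for the 3 arrays of each group and black marks for mean and SD. Prg2, Alox15, Mcpt8, Zbp1, Oasl2 and Csf2rb2 are higher, and Fcmr, Cr2 and Cd3e lower, in all arrays of ITK-SYK mice than in all control arrays, while Syk overlaps.

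In total 160 genes were higher and 205 lower in granulocytes of ITK-SYK mice, 1.66% of the genes tested, of which 65 and 107 changed at least 2-fold. Groups did not overlap for 18.2% of genes, against 10% by chance. Leaving out S6, S9, S12 or S15 gave 81, 97, 95 and 70 higher, and leaving out S6 or S15 gave 117 and 127 lower, while leaving out S10, a T-cell array that shares in the estimate of the spread, gave 283 and 354. Of 50 lists 12 passed upward and 15 downward, and 4 and 3 with an estimated correlation.

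The genotype differences of both cell types were then compared. The test of the difference itself called 734 genes with a more positive change in granulocytes and 510 with a more positive change in T cells. The largest differences between the changes were those of Prg2 (5.10 ± 0.60) and Alox15 (4.10 ± 0.70) on the side of granulocytes, followed by Ear6, H4f16 and Oasl2 (3.11 ± 0.23). On the side of T cells they were those of Ccl5 (-5.01 ± 0.52) and Lilrb4a (-5.00 ± 0.97), followed by Phxr4, Slamf7, a receptor of cytotoxic lymphocytes (-4.21 ± 0.48), and Atp2b4. Of 33 type I interferon genes 17 changed more positively in granulocytes and 0 in T cells (24 and 0 adjusted over the list alone), or 11 without S15 (adjusted p = 1.99e-17, and 0.0479 with an estimated correlation). Among 15 type 1 helper T-cell genes 10 changed more positively in T cells (10 adjusted over the list alone; adjusted p = 6e-12, and 0.079 with an estimated correlation). Only 4 genes were higher in both cell types, Hpse, Il18bp, Il1r2, whose call in granulocytes was lost without S6, S12 or S15 and after renewed quantile normalization, and Plcb3, which were chosen by this overlap, against 4.2 for independent lists. There were 19 genes lower in T cells and higher in granulocytes, against 7.54, with Oas2, Oasl2, Ifit1 and, where its call in T cells holds, Zbp1 among them. The other overlaps were 18 genes lower in both, against 9.66, and 19 higher in T cells and lower in granulocytes, against 5.39. Across genes, which are not independent replicates, the changes correlated at r = -0.08 and rho = -0.09. The split of this contrast was 492 and 613 after renewed quantile normalization, 478 and 609 within cell types, 373 and 711 after cyclic loess and 951 and 415 after subtraction of medians. Leaving out S1, S4, S7, S6 or S15 gave 330, 336, 473, 382 and 298 more positive in granulocytes and 331, 323, 325, 324 and 292 in T cells, and leaving out S9 or S12 gave 481 and 401 more positive in granulocytes.

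**Figure D3:**
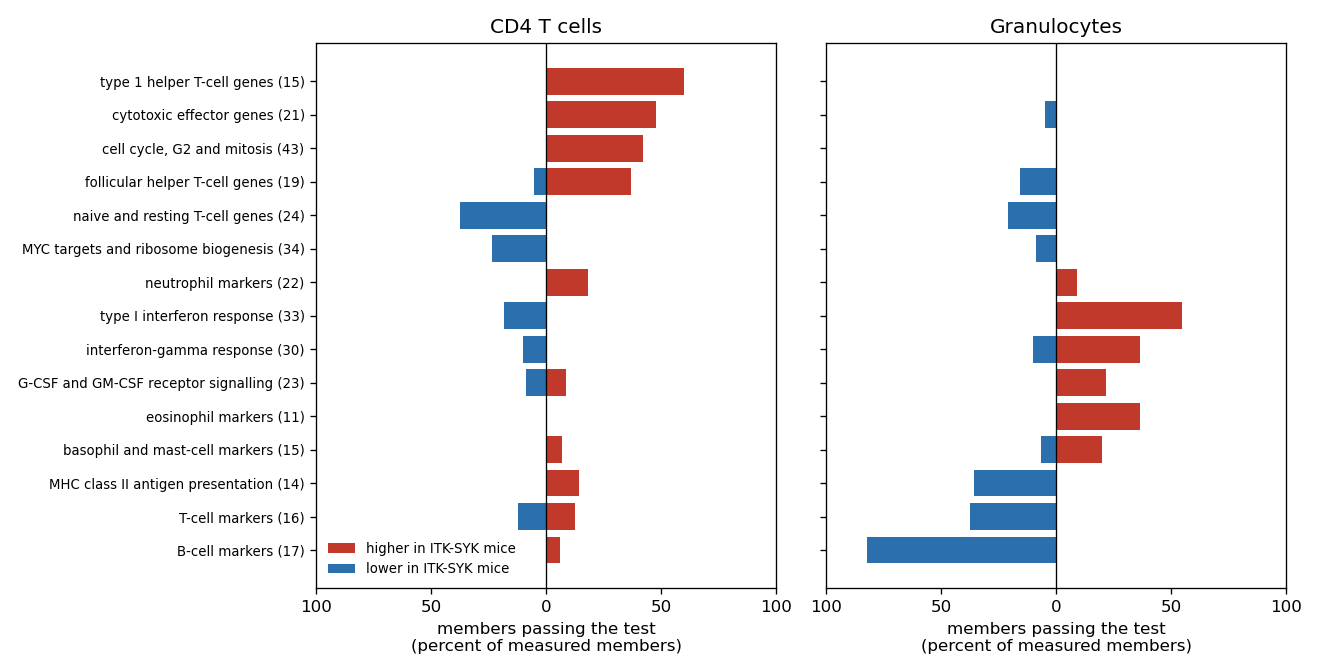
Share of the measured members of 15 gene lists (number measured in brackets) that passed the test upward (red) or downward (blue) in ITK-SYK mice, with CD4 T cells on the left and granulocytes on the right. Bars start at 0 and show, for example, 9 of 15 type 1 helper T-cell genes higher in T cells and 14 of 17 B-cell markers lower in granulocytes.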

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

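The tests on B-cell RNA and on purity, the 3 tests on eosinophil and basophil genes, and for the interferon genes the tests on cells that bring eosinophil genes and on the size of the rise were chosen only after the result was seen, and for 4 of these (purity, eosinophil share, eosinophil receptors, cells that bring eosinophil genes) the test or its bounds were changed after their values were known; the others were planned.

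The genotype difference itself differed between the cell types for 734 genes with a more positive change in granulocytes and 510 with a more positive change in T cells. Of 100 splits of the arrays within both cell types, the real one included, 1 gave as many genes (1244), and the highest of the others gave 316. This share is under 0.05, but the other splits mix genotypes within a group, which widens the spread. They therefore cannot exclude chance differences between the samples of each genotype. For gene lists in the same contrast chance cannot be excluded either: 25 passed, and 16 of the 100 splits gave as many, up to 30. Within a cell type the 10 splits of 6 arrays are too few for a share under 0.05. There the real split called 1612 genes in T cells (highest other 0), 365 in granulocytes (highest other 1) and 7688 between control T cells and control granulocytes (highest other 0), each matched by 1 split, the real one. For lists the real split gave 24 in T cells (1 split, highest other 12) and 27 in granulocytes (2 splits, highest other 27).

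The genes with the largest tested differences between the changes (granulocytes minus T cells) were Prg2 (5.10), Alox15 (4.10), Ear6 (3.93), H4f16 (3.15) and Oasl2 (3.11) on one side, and Ccl5 (-5.01), Lilrb4a (-5.00), Phxr4 (-4.26), Slamf7 (-4.21) and Atp2b4 (-4.03) on the other. All 10 passed with any 1 array left out. Ear6 and Phxr4 had group means below the array medians (2.21 and 3.0 at the lowest), so their sizes are uncertain.

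Lists with a more positive change in granulocytes were type I interferon (median difference 0.89), interferon-gamma (0.85), eosinophil markers (0.91), glycolysis (0.50), p53 targets (0.35) and G-CSF and GM-CSF signalling (0.33). Lists with a more positive change in T cells were type 1 helper (-1.96), cytotoxic (-1.25), follicular helper (-0.79), type 17 helper (-0.72), exhaustion (-0.38), proximal T-cell receptor signalling (-0.35), mitosis (-0.25) and T-cell cytokines (-0.24). The others on that side were markers of B cells (-1.74), T cells (-0.89), natural killer cells (-0.48), monocytes (-0.43), dendritic cells (-0.39) and macrophages (-0.32), immunoglobulin genes (-0.68), MHC class II (-0.59), secondary granules (-0.45), ribosomal proteins (-0.17) and Fc and complement receptors (-0.12). With an estimated correlation 1 of the 6 lists and 4 of the 19 passed. Of the 25 calls, 6 were lost on leaving out some single array: ribosomal proteins (adjusted p up to 0.201, without S18), Fc receptors (0.173, without S18), secondary granules (0.222, without S10), p53 targets (0.0694, without S9), G-CSF signalling (0.0613, without S13) and monocytes (0.0516, without S18).

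Probesets without a single gene name (9528) are not in the gene counts and were tested apart: 477 passed in T cells (238 higher, 239 lower), 73 in granulocytes (29 higher, 44 lower) and 297 in the difference between cell types (115 higher, 182 lower).

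B-cell and T-cell genes were lower in the granulocytes of ITK-SYK mice: 14 of 17 B-cell markers fell, and 55 genes at least 4 log2 units higher in control T cells than in control granulocytes had a median change of -0.34 (-0.44 to -0.24 with 1 array left out), with 83.6% below 0 against 49.7% of all genes. A higher purity that lowers every other cell type alike cannot be told apart from a loss of lymphocyte RNA alone. Of 12 marker lists of cell types other than granulocytes 11 had medians at or below 0 and the highest was 0.008. The falls ranged from -1.60 for B cells to -0.02 for erythroid cells, and eosinophils, which the gate can hold, decide nothing. The erythroid list's median level was 3.74 to 4.17 in control granulocytes, near the array medians, against 6.89 to 7.69 for B-cell markers. A list so low could fall little at any purity, so its small fall does not weigh against a higher purity. A smaller amount of lymphocyte RNA in these sorts may account for the falls of both the B-cell and the T-cell genes. So may lower expression of such genes in the granulocytes themselves or another effect of the genotype, which was not tested. Each of these would give the values of both tests. The B-cell test was set after 14 of 17 markers were seen to fall, so its result adds no support. The abundant B-cell genes Fcmr, Bank1 and Cd22 fell from means of 9.25, 8.99 and 8.25 to 7.18, 7.59 and 6.40, while Cd37 and Btk, which myeloid cells also make, and the T-cell gene Cd3d had 9.56 and 9.90, 8.12 and 8.08, and 10.21 and 10.11. The Gr-1 and CD11b gate would remove most lymphocytes; 16 of the 17 B-cell markers had means above 6 in control granulocytes, and other lists hold 0 of the 17 B-cell and 12 of the 16 T-cell markers.

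Eosinophil and basophil genes were higher in the granulocytes of ITK-SYK mice. Of the 7 that rose, 7 still passed under the normalization with the fewest calls. Their median change was 3.08 to 3.24 under the other normalizations, against 3.21. These 7 were chosen because they passed, and the other normalizations started from the RMA values. Those normalizations gave medians over all genes of -0.01 to 0.03 in granulocytes. Scaling errors of that size are argued against as the source, and larger ones were not tested. A larger share of eosinophils in the sort, varying apart from basophils, can be neither excluded nor supported: over 11 eosinophil markers S12 lay at -0.97 against the mean of S15 and S18, but this is 1 array, only 3 of 15 basophil and mast-cell markers had means above 6 in these mice, and of the risen ones Mcpt8, Cpa3 and Prss34 lay at -0.08, -0.02 and -0.51. The most abundant risen genes Prg2 and Alox15 reached means of 9.49 and 9.12, but of the receptors Siglecf, Ccr3 and Il5ra the highest change was 0.80, below 1.41, the rise set as needed if all markers moved in one ratio (the called genes had a median of 4.23). How much of these receptors' RNA eosinophils give on this array is not known from these data, so whole eosinophils and granule genes switched on in other granulocytes cannot be told apart. The genotype difference stays open, CD11b and Gr-1 do not strictly exclude eosinophils, and other lists hold 2 of the 11 eosinophil and 5 of the 15 basophil and mast-cell markers.

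Type I interferon genes were higher in the granulocytes of ITK-SYK mice, and 1 array alone as the source is argued against by a list median of 0.61 to 0.73 with any granulocyte array left out. Array scaling bears on the calls: of 18 genes that rose 11 passed after renewed quantile normalization, where their median change went from 0.91 (median SE 0.16) to 0.78 (median SE 0.16) and the highest adjusted p was 0.175, and over all genes 313 passed in place of 365. The list's median was 0.54 at its lowest against 0.64. The other normalizations started from the RMA values and gave medians over all genes of -0.01 to 0.03 in granulocytes. Scaling errors of that size are argued against as the source of the size of the rise, and larger ones were not tested. Cells that bring the eosinophil genes could also bring interferon transcripts: the risen interferon genes lay 0.15 higher in S12 than in S15 and S18 while eosinophil markers lay lower, but 1 array decides nothing, so this cannot be told apart from a response of the neutrophils. A response of the granulocytes to the ITK-SYK T cells, in which Ifng rose, stays open as an untested explanation, as does any other effect of the genotype.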

How the results depend on the processing

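The fit without S10 and S6, and leaving out arrays in the comparison of control T cells with control granulocytes, were chosen only after the results were seen; the other alternatives were planned. The direction reversed for 0 named genes on the probeset used or as the mean of a gene's probesets, and 0 lists passed the other way. On 1 of its other probesets the sign differed for Trav7-4 in T cells and for Bcl2, Trav9d-3 and Trav12-2 in granulocytes. In addition, the balance of genes higher and lower reversed in T cells and in the difference between cell types. Of the named genes with a call, 69 of 114 in T cells, 54 of 76 in granulocytes and 10 of 10 in the difference between cell types passed under each alternative, and with any 1 array left out these were 76, 55 and 10.

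In T cells 577 genes were higher and 1035 lower. Renewed quantile normalization, the same within a cell type and cyclic loess left 669, 614 and 560 lower but 687, 631 and 747 higher, so that the larger number of lower genes rests on the scaling, as it does on S1. A fit of T cells alone, with fewer degrees of freedom, left 329 higher and 379 lower. An adjusted p below 0.01 left 263 and 239, and a 2-fold change 246 and 117. In granulocytes (160 and 205) array quality weights gave 307 and 377, an adjusted p below 0.01 gave 65 and 102, and a 2-fold change 65 and 107. In the difference between cell types (734 and 510) renewed quantile normalization gave 492 and 613, the same within cell types 478 and 609, and cyclic loess 373 and 711, so that which side had more genes rests on the scaling too. There a 2-fold change gave 306 and 350, and an adjusted p below 0.01 gave 143 and 201. The stricter thresholds lower counts by construction; for the other changes the cause was not tested.

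Leaving out 1 array gave 331 to 672 higher and 304 to 1373 lower genes in T cells (lowest without S1, highest without S13), 70 to 283 and 117 to 354 in granulocytes (70 without S15, 117 without S6, highest both without S10), and 298 to 943 and 292 to 606 in the difference (lowest without S15, highest without S13 and S10). Between control T cells and control granulocytes it gave 3935 to 4759 higher and 2802 to 3531 lower. Without S10 and S6 the counts were 623 and 856, 143 and 212, 508 and 468, and 4633 and 3381. The correlation of the changes across genes was -0.12 to -0.01 with 1 array left out (-0.01 without S6) and -0.04 without S10 and S6.

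Lists passing upward and downward numbered 19 and 5 in T cells, 12 and 15 in granulocytes and 6 and 19 in the difference. With an estimated correlation they were 0 and 0, 4 and 3, and 1 and 4. With fry, which compares a list with no other genes, 12 passed up and 3 down in T cells, 6 and 7 in granulocytes, and 6 and 12 in the difference. In T cells 3 passed downward after renewed quantile normalization, the same within a cell type, cyclic loess, or without the dimmest 50% of genes. With 1 array left out the ranges were 18 to 20 and 4 to 5, 11 to 14 and 15 to 18, and 4 to 6 and 17 to 20. Signal over background was not used here, so small changes of genes near the lowest values (1.31 to 1.51 across arrays) cannot be told from changes of the background.

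No paired analysis was run, since the labels share no replicate number between groups and leave unstated which T-cell and granulocyte arrays belong together.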

Other observations

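Further lists moved in the T cells. Of 19 dendritic-cell markers 4 rose (adjusted p = 0.004, and 0.14 with an estimated correlation), the integrin Itgae (1.87 ± 0.18), also made by tissue-resident T cells, the chemokine receptor Xcr1 (0.90 ± 0.14), the MHC class II gene H2-Ab1 (0.98 ± 0.16) and Cst3 (0.45 ± 0.12), whose call was lost without S1, S4, S7, S10, S16, S3, S9, S12 or S15 (adjusted p up to 0.136). Of 21 genes of neutrophil migration and chemoattractant receptors 5 rose (adjusted p = 0.00244, and 0.187 with an estimated correlation), among them the integrin Itga4 (1.58 ± 0.20), Ccr2 (2.24 ± 0.35) and Cd44 (1.29 ± 0.24), which activated T cells also use. Of 43 neutrophil activation genes 5 rose, led by the metalloprotease Adam8 (2.50 ± 0.20) and the tetraspanin Cd63 (1.15 ± 0.17), but 3 without S4, S7, S9, S12, S15 or S18 (adjusted p = 0.0097, and 0.362 with an estimated correlation). The basophil and mast-cell list passed with 1 of 15 rising, the cytokine Il4 (adjusted p = 0.0245, and 0.162 with an estimated correlation), but not without S13 (0.0514). Fc and complement receptors passed with 1 of 21 rising, Fcer1g (0.77 ± 0.17; adjusted p = 0.0402, and 0.356 with an estimated correlation), but not without S1 or S10 (0.135 and 0.147), and 0 rose without S1 or S4 or with T cells fitted alone (Fcer1g at adjusted p of 0.000496 to 0.0884 over 24 alternatives). The kinase gene Ern1, a sensor of unfolded proteins, rose by 1.07 ± 0.13 and the stress factor Ddit3 fell by 0.98 ± 0.16, while their list did not pass (adjusted p = 0.463). The oxidase subunit Ncf4 rose by 1.36 ± 0.22 in a list of NADPH oxidase genes that did not pass (adjusted p = 0.463), and Cox6a1, a subunit of the respiratory chain, fell by 0.73 ± 0.12 in another (adjusted p = 0.217).

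In granulocytes further lymphocyte lists were lower. Of 24 naive and resting T-cell genes 5 fell, among them S1pr1 (-1.57 ± 0.13), the transcription factor Foxo1 (-1.25 ± 0.15) and the interleukin-7 receptor Il7r (-1.47 ± 0.21), but 3 without S6, S9, S12 or S15 (adjusted p = 3.55e-06, and 0.209 with an estimated correlation). Of 19 follicular helper genes 3 fell, led by the receptor Slamf1 (-1.72 ± 0.23; adjusted p = 4.51e-05, and 0.0667 with an estimated correlation), and of 26 activation genes of the T-cell receptor 1 fell, the phosphatase Dusp2 (-1.63 ± 0.18; 0.000341 and 0.114). Of 21 cytotoxic genes 1 fell, the cathepsin Ctsw (-0.90 ± 0.15; 0.000469 and 0.263). Of 14 natural killer markers none passed, with Gzma at -1.21 ± 0.29 (adjusted p = 0.0618), while the list's adjusted p was 0.000426 and 0.114 with an estimated correlation. Of 22 immunoglobulin genes none passed, with Igkv4-70 at -1.65 ± 0.39 (adjusted p = 0.0576), and their list had a median of -0.48 (1.09e-05 and 0.184). Of 8 T-cell receptor variable segments 2 fell, but 1 without S1, S4, S7, S6, S12, S15 or S18 (0.000533 and 0.0667). Trav9d-3 changed by -1.57 ± 0.19 on the probeset used and -0.68 to 0.06 on its other 4, and Trav12-2 by -0.87 ± 0.19 (adjusted p = 0.0347, with a range of 0.00645 to 0.375 over 24 alternatives). Of 19 macrophage markers 2 fell, Apoe (-0.80 ± 0.13) and Axl (-0.92 ± 0.16), and 1 rose, Adgre1 (1.43 ± 0.28), which encodes F4/80 and lost its call without S3, S9, S15 or S18 (adjusted p up to 0.106). That list had an adjusted p of 0.000133, and 0.263 with an estimated correlation. The survival gene Bcl2 fell by 1.31 ± 0.19 and the scavenger receptor Cd36 by 0.91 ± 0.14. NADPH oxidase genes rose in 2 of 19 (adjusted p = 0.0043, and 0.281 with an estimated correlation), Nqo1 (0.67 ± 0.14) and Mpo. That count was 0 without S7, S6, S9, S12 or S15, and 1 without S1, S4, S16, S3 or S18. Migration genes rose in 1 of 21 (0.0052 and 0.184), Selplg (0.47 ± 0.11), whose call was lost without any 1 of 10 of the 12 arrays (adjusted p up to 0.2). Neither list passed after renewed quantile normalization.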
